A study of Caenorhabditis elegans with 9 samples.

How the data were processed

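RNA from whole adult Caenorhabditis elegans was measured in 9 libraries, 3 from wild-type worms (WT), 3 from micu-1 mutants and 3 from micu-1; mcu-1 double mutants. Per the labels' protocols, worms were kept at 20 ºC, RNA was taken up in Trizol and purified on a micro column, 5 ng of total RNA was copied into cDNA with SMART-seq2, a full-length method that starts at the poly(A) tail, and the cDNA was fragmented and indexed with Nextera XT and read as single reads of 75 cycles. The method does not mark the strand. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20 and quantified with kallisto, with WBcel235 as the genome build. The kallisto version and the annotation behind its index are not given in the sources used here.

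The deposited file of each library lists 61451 targets, the transcript sequences to which kallisto assigned reads, with an estimated count, a TPM value and a length for each, per the file headers. The estimated counts are not normalized and need not be whole, because kallisto shares a read among the transcripts it fits, so related transcripts and paralogs trade reads and a value of 0 can be an outcome of that sharing. The TPM values were scaled by the authors' kallisto run to transcript length and to the same total in each library. The authors also deposited 1 table of whole-number counts for the series, with 27219 rows that carry transcript-style names.

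Targets carry a running number and no gene name, so no value here is assigned to a gene. The names in the series table were tested for this purpose and not used. Of its 11110 rows with over 50 counts, 10255 equalled the truncated estimated counts of exactly 1 target in all 9 libraries. For 9803 of these the row's name has a transcript length in the Ensembl annotation of the same build, and 5 had the length of the target whose counts they held, where shuffled names gave up to 8 in 100 shuffles. Length alone could not supply names either. A total of 395 targets had a length shared with no other target and with exactly 1 annotated gene, and 308 to 340 did when the annotated lengths were shifted by 5 to 13 bases. Names from the order of targets in the list were tried first, and tests on those names, of the gene lists fixed before the data were examined and of micu-1 among them, were run and seen. They were dropped because the rules set for the work do not allow names to be taken from order, not because a test showed them to be wrong, and no result here uses them. The labelled genotypes therefore have no check from expression here, and no result for the gene lists, cell type markers or named genes is reported.

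The plan was to test counts per gene. Because targets could not be summed into genes, each target was tested by itself, on estimated counts rounded to whole numbers, which departs from the plan. Tests used edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr by group and the quasi-likelihood test, in 1 fit of all 9 libraries with a mean per group. A target was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all targets tested. Standard errors are the log2 fold change divided by the root of its F statistic. CPM values use the TMM-scaled totals. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group, which covers counting error only. The rule fixed for naming genes was kept for targets without its need for a gene symbol and shortened to 2 rises and 2 falls in micu-1 against WT: adjusted p under 0.05, a mean log2 CPM of at least 2, no overlap between the libraries of the groups, and the largest log2 fold changes.

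Estimated counts summed to between 12674470 and 19047383 per library. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries of a group agreed within sampling noise, the lowest chi-square statistic per degree of freedom being 19.6 over targets with at least 20 counts in the pair. On simulated data for micu-1 against WT, drawn from the WT means with the spread of the real libraries, 200 targets were changed and 16242 targets passed the filter. The 200 were drawn from all 20840 targets of the real test. A target at 0 in WT stayed at 0 at any fold, and a changed target that failed the filter was counted as not recovered. The test recovered 2 of 60 targets changed 2-fold, 18 of 70 changed 4-fold and 34 of 70 changed 16-fold, and called 0 in the wrong direction and 0 of the unchanged targets. Among targets in the upper 50% by abundance it recovered 2 of 34, 18 of 36 and 27 of 35. The 16-fold changes and the division by abundance were added after a first run at 2-fold and 4-fold had recovered few. In this simulation 2-fold changes were thus mostly missed, also among abundant targets. The low recovery among scarce targets includes any that stayed at 0 or were not tested, so it does not measure the test alone. The simulation changed 200 targets, whereas 57.03% of targets tested were called in the real comparison with WT. Its cut on the adjusted p was therefore stricter, and these shares do not give the share missed in the real comparison.

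The alternatives set before the data were examined were DESeq2's median-ratio size factors in edgeR, the DESeq2 1.42.0 Wald test, limma 3.58.1 on log2(TPM + 1) and on log2(TPM + 0.1), no filter beyond a nonzero total, a mean CPM of at least 10, a fit of the 2 groups compared, the replicate number as a block, robust empirical Bayes and leaving out each library in turn. Added after seeing the data were a test of the rows of the series table, removal of the 10 most abundant targets, removal of each library's loess trend of log2 CPM with log2 length (span 0.5), and thinning of each library to the smallest total. Comparisons that share libraries were set beside 20 simulations of unchanged groups and beside the overlap that independent lists of the same sizes would have. That overlap was computed over all tested targets together. Calls were more frequent among abundant targets, so it tends to be too low. The 3 micu-1 libraries were also divided in all 6 ways so that different ones entered the comparison with WT and the comparison with the double mutant, and the 3 WT libraries likewise between the comparisons with each mutant, in edgeR fits that assume a lone library to vary like the other groups. Principal components were taken from log2 CPM with a prior count of 2. Shares of counts were compared by two-sided exact permutation tests, which with 3 libraries against 3 cannot give a p below 0.1.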

Results

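The series profiled whole adult worms of 3 genotypes, with 3 libraries each. micu-1 encodes the worm counterpart of MICU1, the gatekeeper subunit of the mitochondrial calcium uniporter, and mcu-1 encodes the counterpart of MCU, its pore-forming subunit. WT worms were the N2 Bristol strain and are labelled as 5 days old. The micu-1 mutants (strain BAN362, allele bon20) and the double mutants (strain BAN378, bon20 with mcu-1 allele jul154) are labelled as 4 days old. Both mutant strains are listed with the balancer chromosome nT1[qIs51], and the labels do not say which of their progeny were collected. Genotype and labelled age therefore change together in each comparison with WT, and the double mutant against the micu-1 mutant is the comparison at 1 labelled age.

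Estimated counts totalled 13662364, 14629342 and 17628377 in the WT libraries, 19047383, 13856431 and 15231761 in the micu-1 libraries and 18686303, 12674470 and 13705642 in the double mutant libraries. Of the 61451 transcript targets, 35215 had a count in any library and 20840 had enough counts to be tested. Between 22123 and 24371 targets were detected at 1 count or more in a library. Targets are given by number because they are not paired with gene names.

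The genotypes separated along the first principal component, which held 59.5% of the variance. WT libraries scored between -250.9 and -234.2 on it, micu-1 libraries between 134.3 and 136.2 and double mutant libraries between 104.1 and 111.7. Across tested targets, Pearson's r of log2 CPM was 0.886 to 0.892 between WT libraries, 0.834 to 0.849 between micu-1 libraries and 0.814 to 0.831 between double mutant libraries. It was 0.497 to 0.514 between WT and micu-1 libraries, 0.538 to 0.570 between WT and double mutant libraries, and 0.811 to 0.839 between the 2 mutants, close to the values within each mutant. Targets are not independent replicates, so these are descriptions of the libraries. The second component held 7.18% and set replicate 1 of the double mutant, at 160.9, apart from the other 8 libraries, which lay between -53.5 and 3.41.

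**Figure D1:**
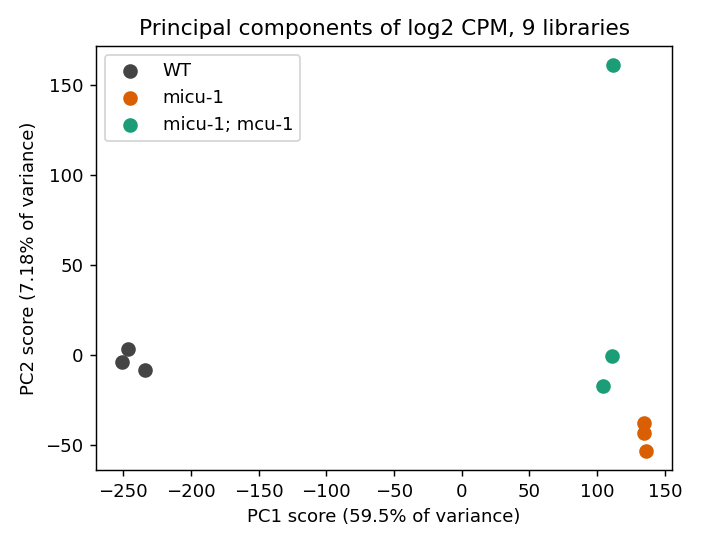
Scores of the 9 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, 1 point per library, coloured by genotype. WT libraries lie between -250.9 and -234.2 on the first component and the mutant libraries between 104.1 and 136.2.

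The first comparison asked which transcripts differ between micu-1 mutants and WT. Of 20840 targets, 6484 were higher and 5402 lower in the micu-1 mutant, together 57.03% of those tested (edgeR quasi-likelihood test, adjusted p under 0.05). The changes were large. The median change among called targets was 4.97-fold for those higher and 4.11-fold for those lower, and 1867 of the higher and 1005 of the lower targets had a fitted change of over 16-fold. The libraries of the groups did not overlap for 14663 targets, or 70.4%, where chance gives 10%.

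A set of transcripts was seen in 1 of the genotypes and not in the other. 341 targets had 0 counts in all 3 WT libraries and at least 50 counts in each micu-1 library, and 188 had 0 counts in all 3 micu-1 libraries and at least 50 in each WT library. Target 21472, a transcript of 454 bases, stood at 661 ± 72.5 CPM in the micu-1 mutant (SD, n = 3) and at 0 counts in WT, which makes it at least 13788-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 4.19e-07). Target 20940, of 416 bases, stood at 344.9 ± 56.8 CPM and at 0 counts, at least 7242-fold higher (edgeR adjusted p = 2.29e-06). Target 53793, of 3967 bases, stood at 155 ± 20.4 CPM in WT and at 0 counts in the micu-1 mutant, at least 2360-fold lower (edgeR adjusted p = 0.000116). Target 13591, of 876 bases, stood at 107 ± 18.2 CPM in WT and at 0 counts in the micu-1 mutant, at least 1635-fold lower (edgeR adjusted p = 2.77e-05). Because kallisto divides reads among related transcripts, a 0 for 1 target does not show that its gene was silent.

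Short and long transcripts moved apart. In the shortest 25% of tested targets, of 55 to 864 bases, 2079 targets were higher in the micu-1 mutant and 1001 lower, with a median log2 fold change of 0.92. In the longest 25%, from 1985 bases up, 1149 were higher and 1636 lower, with a median of -0.39. Spearman's rho between length and log2 fold change across targets was -0.15. The balance of directions depended on the scale. The median log2 fold change over all tested targets was 0.31 with TMM factors and -0.15 on log2(TPM + 1), where 5654 targets were higher and 7661 lower by limma. With the length trend removed, chosen after seeing the data, the median was 0.03, with 5755 higher and 6049 lower.

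The second comparison set the double mutant against WT. Here 6236 targets were higher and 5312 lower in the double mutant, 55.4% of those tested (edgeR quasi-likelihood test). The median change was 5.00-fold for those higher and 3.60-fold for those lower. Target 21472 stood at 648 ± 58.8 CPM in the double mutant (SD, n = 3), at least 13316-fold above WT, and target 20940 at 250 ± 54.1 CPM, at least 5145-fold above WT. Target 53793 stood at 0.462 ± 0.437 CPM and target 13591 at 0.0540 ± 0.0936 CPM, the latter from 2 counts in all. All 4 were called against WT by edgeR. The shortest 25% again held more higher than lower targets, 2028 against 987, and the longest 25% held fewer, 1035 against 1655. On log2(TPM + 1) limma called 4973 higher and 7894 lower, with the median at -0.26 where TMM gave 0.22.

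Transcripts changed alike in both mutants. 5874 targets were higher in both and 4788 lower in both, together 10662, and 14 were called in opposite directions. Simulated unchanged groups that share the WT libraries gave 0 targets changed alike in 20 simulations, in which nearly no target is called against WT, and independent lists of these sizes would share 3317. Across targets, Pearson's r of the log2 fold changes was 0.90, where shared WT libraries alone gave 0.49, and the covariance was 10.2 against a simulated 0.57. The value of 0.90 holds both the effects and the shared libraries. Between comparisons with different WT libraries r was 0.619 to 0.631, with fewer WT libraries in each comparison and more targets, 25055, past the filter. With different WT libraries in the 2 comparisons, chosen after seeing the data, 7794 to 8319 targets changed alike over 6 divisions and 16 to 31 in opposite directions, where independent lists give 1811 to 1961 alike. A total of 218 targets had 0 counts in all WT libraries and at least 50 in each of the 6 mutant libraries, and 95 had 0 counts in all mutant libraries and at least 50 in each WT library.

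**Figure D2:**
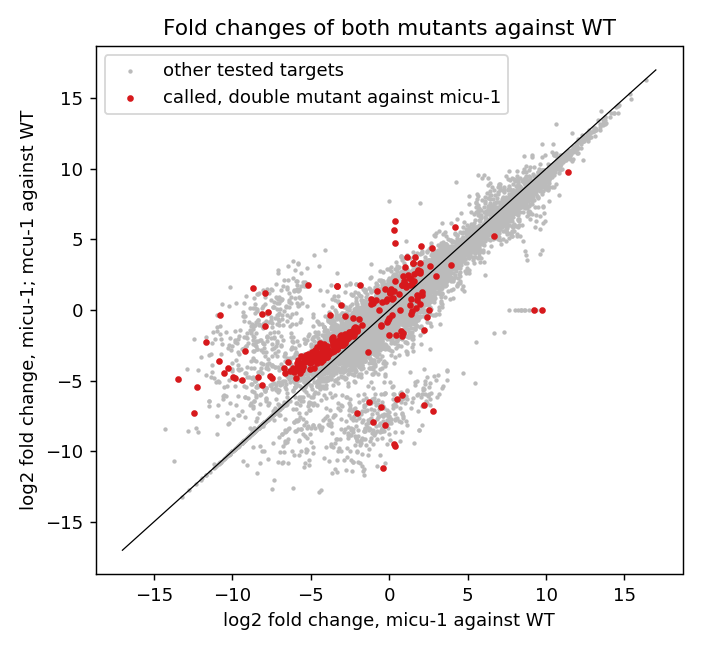
Log2 fold change of each tested target in the micu-1 mutant against WT (x axis) and in the micu-1; mcu-1 double mutant against WT (y axis), with the line of equal change. Grey points are tested targets and red points are the 282 called between the mutants, and the values correlate across targets with Pearson's r of 0.90.

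The third comparison, at 1 labelled age, asked what loss of mcu-1 adds in the micu-1 mutant. It called 282 targets, 1.35% of those tested, of which 237 were higher and 45 lower in the double mutant (edgeR quasi-likelihood test). The median change was 2.19-fold for those higher and 3.19-fold for those lower. Of the 237, 197 lay in the most abundant 25% of tested targets. The libraries of the mutants did not overlap for 19.7% of targets, where chance gives 10%. Of the 4 targets named above, 0 were called: the log2 fold change was -0.03 ± 0.11 (SE) for target 21472 and -0.46 ± 0.20 for target 20940, and target 53793 had 16 counts in the double mutant against 0. The count of 282 rested on the test, the filter, the model, the features tested and the libraries used. DESeq2, run on 34194 targets with its own default filter on mean count in place of filterByExpr, called 1164. edgeR called 80 on the 2 mutants alone, 181 without the filter and 72 with the replicate number as a block. In the series table it called 154 of 10233 rows tested, or 1.505%, a share near the 1.35% of targets. Leaving out 1 library gave between 0.537% of targets, without micu-1 replicate 3, and 1.09%, without replicate 3 of the double mutant. The count was 152 to 165 without 1 WT library, 185 without micu-1 replicate 1, 157 without micu-1 replicate 2 and 145 without replicate 2 of the double mutant. Without replicate 1 of the double mutant, which stood apart on the second component, it was 193, or 0.865% of targets tested, which is within 1.5 times by count and beyond it by percent. On log2(TPM + 1) limma called 130 higher and 84 lower.

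Targets called between the mutants mostly differed in the direction of the WT level. Whether the double mutant stopped short of that level or passed it was not counted. Of the 237 targets higher in the double mutant, 193 had been lower in the micu-1 mutant than in WT, 30 had been higher and 14 had not been called. Of the 45 lower targets, 25 had been higher in the micu-1 mutant than in WT, 5 lower and 15 not called. The 218 targets that went the opposite way compare with 35 that went the same way. The comparisons share the micu-1 libraries with opposite sign, which by itself favours opposition: unchanged simulated groups gave a correlation of fold changes of -0.50, against -0.32 observed, with a covariance of -0.55 against -1.66. Their count of opposed targets, 0, says little, since nearly no target is called against WT without an effect. Independent lists would give 75.4 opposed targets, a value that tends to be too low because calls gathered in abundant targets. The 218 holds both the effects and the shared libraries. With different micu-1 libraries in the 2 comparisons, 50 to 116 targets were opposed over 6 divisions and 5 to 15 went the same way, where independent lists give 11.8 to 24.6 opposed. DESeq2 gave 828 opposed targets, edgeR gave 145 without the filter, 54 on 2 groups at a time, 57 with the block and 332 with the length trend removed, and the count was 94 without micu-1 replicate 3, 129 without micu-1 replicate 2, 118 without replicate 2 of the double mutant, and 117 to 131 without 1 WT library.

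Across targets changed over 2-fold in the micu-1 mutant, most of them not called between the mutants, the change in the double mutant was nearly as large. Of the 4772 targets called lower by more than 2-fold in the micu-1 mutant, the median ratio of the log2 fold change in the double mutant to that in the micu-1 mutant was 0.88, with quartiles of 0.76 and 1.00. For the 5983 called higher it was 0.95, with quartiles of 0.87 and 1.04. Both changes are taken against the same WT libraries, which draws the ratios towards 1, and no ratio with different WT libraries was computed. Selection on the micu-1 mutant lowers these ratios. When targets were instead selected on the double mutant, the ratio of the micu-1 change to the double mutant change was 1.06 for 4530 lower targets, with quartiles of 0.917 and 1.225, and 1.02 for 5745 higher targets, with quartiles of 0.919 and 1.103. With either selection the medians lay on the side of a smaller change in the double mutant, for lower and higher targets, while the quartiles reached or spanned 1.

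Counts were gathered in fewer targets in the mutants than in WT. The same target, of 3509 bases, was the most abundant in all 9 libraries and held 13.5%, 12.9% and 9.66% of counts in the WT libraries, 23.7%, 26.2% and 27.5% in the micu-1 libraries and 43.4%, 28.4% and 30.9% in the double mutant libraries. The 10 most abundant targets held 23.4 ± 1.93% of counts in WT, 38.9 ± 1.68% in the micu-1 mutant and 46.2 ± 6.81% in the double mutant (SD, n = 3). Each pair of genotypes was separated without overlap, with an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give. Without the most abundant target the mutants overlapped (exact permutation p = 0.2), and each stayed apart from WT. The number of targets that together held 50% of counts was 319, 309 and 370 in WT, 54, 40 and 37 in the micu-1 mutant, and 5, 35 and 26 in the double mutant.

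**Figure D3:**
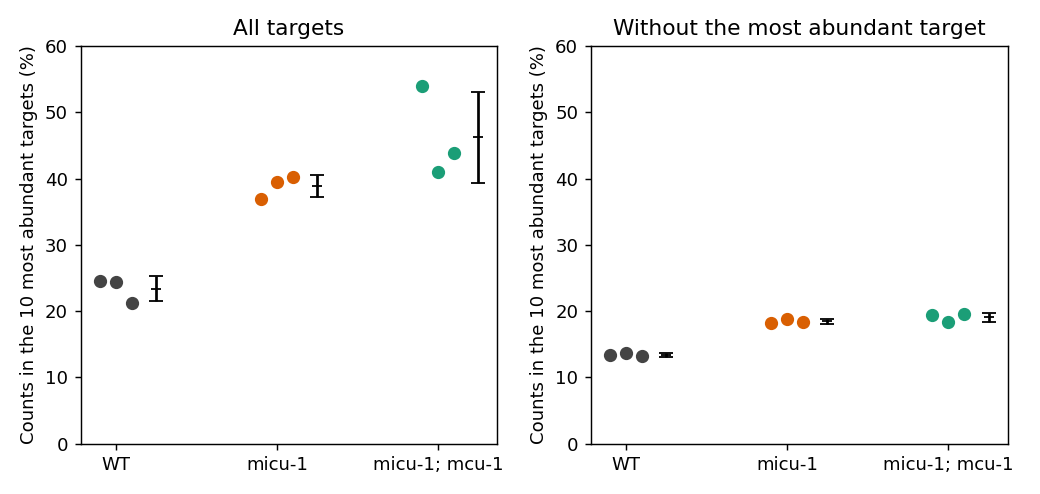
Percent of each library's counts in its 10 most abundant targets (y axis) by genotype (x axis), over all targets (left) and without the most abundant target (right). Points are libraries and bars are the mean and SD of 3 libraries, and WT lies at 23.4 ± 1.93% on the left and 13.4 ± 0.260% on the right, below both mutants.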

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

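The removal of abundant targets, the removal of the length trend, the thinning and the test of the series table were chosen after seeing the data; the other settings were set before. Values are percent of targets tested, with counts in brackets. Whether a setting moved a result by over 1.5 times was judged on counts, since percents also change with the number tested: with no filter the count for micu-1 against WT was 11131 and the percent 32.5. The counts against WT and the count changed alike stayed within 1.5 times with DESeq2 size factors, the DESeq2 test, limma on either TPM scale, no filter, the 2 groups alone, robust estimation, the length trend removed, thinning and the removal of the 10 most abundant targets. A mean CPM of at least 10, which leaves 7880 targets, gave 77.4% (6099 targets) for micu-1 against WT, 76.0% (5989) for the double mutant against WT and 72.2% (5691) alike. The series table, with 10233 rows tested, gave 54.8% (5607), 53.65% (5490) and 49.1% (5029), 1.505% (154) between the mutants and 1.202% opposed. Fewer features were tested in both.

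Between the mutants 1.35% changed (282) and 1.05% were opposed (218). The DESeq2 test gave 3.40% (1164) and 2.42% (828), no filter 0.529% (181) and 0.424% (145), and the 2 groups alone 0.437% (80) and 0.295% (54). The DESeq2 percents are of all 34194 targets run, with any that its own filter on mean count left without an adjusted p. With the length trend removed 1.59% (332) were opposed. The cause was not tested for these. A mean CPM of at least 10 gave 5.19% (409) and 4.12% (325), of fewer targets tested and within 1.5 times by count. The replicate block gave 0.345% (72) changed and 0.274% (57) opposed. Replicate numbers do not pair the libraries: deviations from group means of libraries with the same number correlated between -0.0285 and 0.0155, and 3 of 9 libraries correlated best with their own number. The block moved the other counts by less than 1.5 times.

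Leaving out each library in turn gave 48.6% to 53.2% for micu-1 against WT, 47.4% to 50.6% for the double mutant against WT, 44.4% to 45.4% alike, 0.537% to 1.09% between the mutants and 0.424% to 0.794% opposed. The 4 named targets kept their direction and call against WT in all settings that tested them. They were picked as the largest changes in the same libraries, so this says little about other targets. Target 53793, not called between the mutants, was called by DESeq2 (adjusted p = 0.00176) and without replicate 1 of the double mutant (edgeR adjusted p = 0.0281). Gene lists, cell type markers, named genes and sums per gene have no results here, since the files do not pair targets with gene names; lists run on names from target order were dropped because the rules set for the work do not allow such names. Fewer scarce targets were called: between the mutants 3.78% of the most abundant 25% were called higher and 0.480% lower, against 0.0576% and 0.134% of the least abundant.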

Other observations

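The tests of target length, library depth, the single most abundant target, the splits of all 9 libraries and the divisions of the micu-1 libraries were set before their results were seen, but after the size of the difference from WT and, for the splits and the most abundant target, the values per library had been seen; the divisions were also set after the count of opposed targets. The other tests were chosen after. The draw of the 9-library splits was changed once after a first result, to leave out relabellings of the real groups, and gave the same shares. The number of transcripts detected did not follow the gathering of counts. WT libraries had 24234, 22123 and 22562 targets at 1 count or more, micu-1 libraries 24143, 23570 and 24371, and double mutant libraries 23023, 23645 and 22549. Targets of 4000 bases or longer held 14.4%, 14.9% and 14.8% of counts in WT, 11.6%, 11.8% and 10.9% in the micu-1 mutant and 8.96%, 10.2% and 11.8% in the double mutant. The most abundant target is shorter than this. Its larger share in the mutants lowers the share of all other targets, so these values do not show a fall of long transcripts among the rest. Between the mutants, 5 targets had 0 counts in all micu-1 libraries and at least 50 in each double mutant library, and 8 had the reverse, against 341 and 188 between WT and the micu-1 mutant.

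Over 50% of tested targets differed between each mutant and WT. A few targets that take most of the counts would shift the rest by 1 common amount, but the interquartile range of the log2 difference between the micu-1 and WT means was 3.453 over tested targets, against 0.653 to 0.958 between 2 libraries of the same group. Removing each library's trend with target length left 11804 calls where 11886 had been made, 10939 of them in the same direction as before, so a length trend may change the balance of directions and does not account for the number of calls. Thinning every library to 12674390 counts left 11762 calls. The thinned totals include the most abundant target, whose share was larger in the mutants, so depth over the other targets stayed unequal. Genotype, strain and labelled age cannot be separated here, because WT and mutants differ in all of them at once. RNA quality and handling are not given in the labels and were not tested.

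Of the targets lower in the micu-1 mutant than in WT, 193 were called higher in the double mutant than in the micu-1 mutant, 5 lower, and 5204 were not called. The targets that were called between the mutants mostly went the opposite way from their change in the micu-1 mutant against WT. With different micu-1 libraries in the 2 comparisons, opposed targets numbered at least 3.819 times what independent lists give in each of 6 divisions. That ratio tends to be too high, because calls gathered in abundant targets. In the most abundant 25%, 45.57% were lower and 37.16% higher in the micu-1 mutant than in WT. Abundance by itself would thus give similar numbers each way, but 50 to 116 were opposed and 5 to 15 went the same way. Shared micu-1 libraries therefore do not account for this by themselves. The correlation of fold changes lay between -0.123 and -0.102 over the divisions. The divisions remove noise of single libraries only. A deviation common to all micu-1 libraries would still enter both comparisons with opposite sign, and the divisions cannot decide on it. A single double mutant library is not the source of the whole pattern, since leaving out each in turn left at least 118 opposed targets, the lowest being without replicate 2. A hypothesis is that loss of mcu-1 partly returns some transcripts to WT levels in micu-1 mutants. A difference in developmental timing between the mutant strains may give the same pattern. Neither was tested, and WT, micu-1, mcu-1 and double mutant worms measured at 1 age would be needed to test them.

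Counts were gathered in fewer targets in the mutants. The single most abundant target does not account for the difference from WT by itself: without it, the lowest mutant share of the top 10 lay 4.50 percentage points above the highest WT share, at 18.4 ± 0.352% in the micu-1 mutant, 19.1 ± 0.688% in the double mutant and 13.4 ± 0.260% in WT (SD, n = 3; exact permutation p = 0.1 for each mutant against WT, the smallest possible). The mutants overlapped without it (exact permutation p = 0.2), so their separation over all targets rests on that target. Without it, 529 to 559 targets held 50% of counts in WT and 147 to 184 in the mutants. What these targets encode is open, so their shares need not reflect a change in messenger RNA. Whether the genotype, the labelled age, the RNA input or RNA quality set these shares is open too.

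For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave the highest count in each comparison: 11886 against at most 1 in the other splits for micu-1 against WT, 11548 against 0 for the double mutant against WT, and 282 against 7 between the mutants, so 1 of 10 splits reached the real count each time. Of 60 splits of all 9 libraries, the real one included, 1 gave as many targets changed alike, and the highest of the others was 10586. For opposed targets 2 of 60 gave as many as the real split, with a highest of 10570. Both highest values came from the 4 of 59 drawn splits that kept the WT libraries as 1 group, and the other drawn splits gave at most 1 target on either count, so the shares of 60 reflect the separation of WT from the mutants and do not decide on chance for either count. Of the 20 ways to assign the 6 mutant libraries with WT in its place, chosen after, the real one gave the most opposed targets, 218, against 78 with the mutants exchanged and at most 6 in the rest, which are too few for a share under 0.05. All of them gave 10540 or more targets changed alike, so that count does not depend on how the mutant libraries are divided.

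The names in the deposited series table are a point for anyone who uses it. Of 9803 rows that hold the counts of 1 target and have a name with an annotated length, 5 fit the target's length, no more than the 8 that shuffled names reached.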
